A study of Mus musculus with 6 samples.

How the data were processed

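Gene expression was measured on Affymetrix one-colour arrays in 6 pieces of mouse colon tumour, 3 from mice of wild-type genotype and 3 from mice in which p53 was deleted in the intestinal epithelium. Per the labels' protocols, the mice were of FvB background, and exons 2 to 10 of the floxed p53 gene were removed by Cre recombinase driven by the villin promoter, in its constitutive or its tamoxifen-dependent form. Which of both forms a sample carried is not given in the sources used here. Tumours were induced with azoxymethane, a colon carcinogen, injected at 10 mg/kg once a week for 6 weeks, and were taken after 16 to 20 weeks of growth. A tumour piece holds epithelium together with stroma and immune cells, in which the gene was not targeted.

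The deposited values are probe set intensities on a linear scale, made by the authors with Affymetrix Expression Console 1.1, per the submitters' processing notes. RNA was labelled with biotin by the GeneChip WT kit, per the labels' protocols. The background correction, normalization and summary method are not given in the sources used here. The range of the values, from 1.03 to 9167, showed that they were not logarithms. The median intensity lay between 5.53 and 5.72 in the 6 samples and the upper quartile between 26.3 and 28.5, so no further scaling was applied in the main test. For such arrays the number of samples limits the precision.

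The table held 35557 probe sets. The platform annotation gave 1 gene symbol for 21789 of them and several for 1621, and 12147 were not listed in it and are unnamed here. Of the named probe sets, 21698 matched a RefSeq gene of assembly GRCm38.p6 by gene identifier, and 0 symbols needed updating. The assembly of the array is not given in the sources used here, so RefSeq was used for names and for the order of genes along chromosomes, and no coordinates are printed. Where a gene had several probe sets, the one with the highest mean over the 6 samples was used, which left 19938 genes. Probe sets with several symbols were not named, and some members of the gene lists are therefore not analysed here. No probe set was named for Trp53, the targeted gene, so its level is not analysed here and the genotype labels were not checked against it.

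Values were taken as log2(intensity + 1). Fold differences are on this scale, which understates the change of dim genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All 6 samples entered the fit, with no covariate. An exact permutation test of 3 against 3 samples cannot go below p = 0.1, so none was used for single genes. Nothing in the labels says that the samples of a group came from separate animals, and a number in the descriptions is shared by wild-type samples 1 and 2 and by knockout samples 2 and 3. The p-values then measure only the spread between these samples, which may be technical in part.

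Before the data were examined, 33 gene lists were fixed for pathways and cell types that a colon tumour can hold. Several of them take up the inflammation and invasion named in the series title. The list of sex-linked genes was given as values only, and 32 lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists. The same lists were tested with a correlation estimated from the data, with fry and with ranks. Members of a list were also adjusted over the list alone. Genes with a mean above 4 on the log2 scale are called clearly measured, a limit chosen after the data were seen. The rule for named genes, fixed at the same time, took up to 12 genes per direction with the largest difference among genes past the threshold whose groups did not overlap. Open places were filled in order of unadjusted p among genes differing by at least 1 on the log2 scale without overlap, and these are described as not past the threshold. The rule also took the 3 members of each list with the smallest p, and for some lists not all 3 are printed here. Immunoglobulin genes, predicted genes and some other classes were counted but not named by that rule.

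The gene test was checked on simulated data with the real means and spreads of 19938 genes, 200 of them changed in each of 10 runs. It recovered 23% of genes changed by 0.5 on the log2 scale, 73.4% of those changed by 1 and 95.6% of those changed by 2, and 4.06% of all calls were false. Genes were simulated without correlation between them. Where fewer genes are changed, the Benjamini-Hochberg threshold is stricter and a smaller share would be recovered. The list tests were checked in 50 runs on the 32 lists. Where genes were not correlated, camera with the preset correlation, camera with the estimated correlation and fry called 0.4%, 0% and 0.4% of unchanged lists, and 100%, 92.8% and 95.6% of lists shifted by 0.5. Where genes of an unchanged list were correlated by 0.2, camera with the preset correlation called 21.6% of such lists, with the estimated correlation 0%, and fry 0.8%. Where such lists were shifted by 0.5, the 3 tests called 98.8%, 32% and 69.6%. A call with the preset correlation alone can thus come from genes that vary together between samples, and in lists correlated by 0.2 the estimated correlation misses most shifts of 0.5, though not in uncorrelated ones. The correlation estimated from the data was -0.024 in the YAP list, 0.039 in the p53 target list and 0.059 in the colonocyte list, 0.29 in the matrix protease list and 0.52 in the fibroblast list. Correlations above 0.2 were not simulated, so the share of false calls in lists such as the matrix protease and fibroblast lists is not known.

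The alternatives were quantile normalization, centring on the median, leaving out dim probe sets, averaging the probe sets of a gene, a mean-variance trend with robust eBayes, array weights, the replicate number as a block, the shared number averaged or as a random block, a pseudocount of 16, an adjusted p threshold of 0.1, all probe sets, and leaving out each sample in turn. The closing part gives their effect. Figures were drawn with matplotlib 3.10.9.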

Results

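Expression was compared between azoxymethane-induced colon tumours of 3 wild-type samples and 3 samples with p53 deleted in the intestinal epithelium (p53 knockout). The series title states the question, which is whether epithelial p53 loss goes with an inflammatory surrounding and with invasion. The 6 arrays were alike in overall signal, with median intensities between 5.53 and 5.72. Across genes, which are not independent replicates, Pearson's r between samples lay between 0.9781 and 0.9914. By r the samples did not all group by genotype. Wild-type sample 1 (0.9888) and wild-type sample 3 (0.9875) correlated best with knockout sample 3, above their r with other wild-type samples (0.9865 to 0.9879). The first principal component held 40.1% of the variance and separated the genotypes, with knockout sample 1 farthest from the wild type (30.1) and knockout sample 3 nearest (5.66). The targeted gene is not analysed here, so the labels were not checked against it.

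In the knockout tumours, 11 genes were higher and 6 lower than in the wild type. The largest rise among them was in Cxcl10, an interferon-inducible chemokine, which went from 3.90 ± 0.15 to 6.39 ± 0.47 (SD, n = 3 each, log2 scale), a 5.63-fold difference with adjusted p = 0.0377. Adamts1, a secreted metalloprotease, rose from 3.01 ± 0.08, a dim level, to 4.65 ± 0.21, or by 1.64 (adjusted p = 0.0214), and by 0.80 with a pseudocount of 16. The smallest p belonged to Dsg4, a desmosomal cadherin, which fell from 4.67 ± 0.12 to 2.93 ± 0.05, a log2 difference of -1.74 (SE 0.0944, adjusted p = 0.00438), and of -0.84 with a pseudocount of 16. Saa1, an acute phase protein, fell from 6.79 ± 0.29 to 5.26 ± 0.11, or by 1.53 (adjusted p = 0.0377). The probe set of its close paralog Saa2 was dim, at 2.95 ± 0.08 and 2.86 ± 0.04, and did not pass (difference -0.089, adjusted p = 0.773).

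The other named genes past the threshold covered secreted, signalling and metabolic proteins. Cpe, a prohormone-processing carboxypeptidase, rose by 1.90 (SE 0.206), Moxd1 by 1.63 (SE 0.149) and Lifr, the receptor of leukaemia inhibitory factor, by 1.25 (SE 0.124). Dusp6, a phosphatase that inactivates ERK kinases, rose by 1.02 (SE 0.106) and Apobec3, an antiviral cytidine deaminase, by 1.02 (SE 0.115). Wfdc2 rose by 0.98, the calcium-binding protein Gca by 0.86 and the collagen gene Col14a1 by 0.82. Bcl2l15, of the Bcl-2 family, fell by 1.77 (SE 0.201), Ppp1r14d, an inhibitor of protein phosphatase 1, by 1.23 (SE 0.133) and the acyl-CoA thioesterase Acot11 by 0.87 (SE 0.0912). Adjusted p for these 11 genes lay between 0.0377 and 0.0458. Outside the naming rule, 2 more genes passed, the immunoglobulin heavy chain Ighm with a log2 difference of 1.76 and the predicted gene Gm11545 with -1.43, both named after their values were seen.

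Further genes differed by at least 1 on the log2 scale without overlap between the groups but did not pass the threshold. Ier3, an immediate early gene, differed by 1.28 (adjusted p = 0.0551) and Ift57, a gene of cilia transport, by 1.06 (adjusted p = 0.0683). On the lower side, the aminopeptidase Xpnpep2 differed by -2.55 (adjusted p = 0.0696), the hedgehog ligand Ihh by -1.18 (adjusted p = 0.0734) and the epithelial tyrosine kinase Ptk6 by -1.37 (adjusted p = 0.0755). The values were -1.34 for the transcription factor Sox17, -1.22 for Tmem253, -1.11 for Tmem37 and -1.67 for the carboxylesterase Ces2e, with adjusted p between 0.115 and 0.126.

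Of the 19938 genes, 17 passed the threshold in limma's test, and in all 17 the groups did not overlap. Without overlap were 3052 genes, or 15.3%, where chance gives 10%. At an unadjusted p under 0.05 there were 2154 genes, 1221 higher and 933 lower. No gene passed when samples sharing a number were averaged (2015 genes at an unadjusted p under 0.05 in limma) or with a pseudocount of 16 (1952 genes). The count was 16 without wild-type sample 1, of which 7 were among the 17, and 2 without knockout sample 1, of which 1 was. It was 1 without wild-type sample 2, 1 without wild-type sample 3, 2 without knockout sample 2 and 3 without knockout sample 3, all among the 17.

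**Figure D1:**
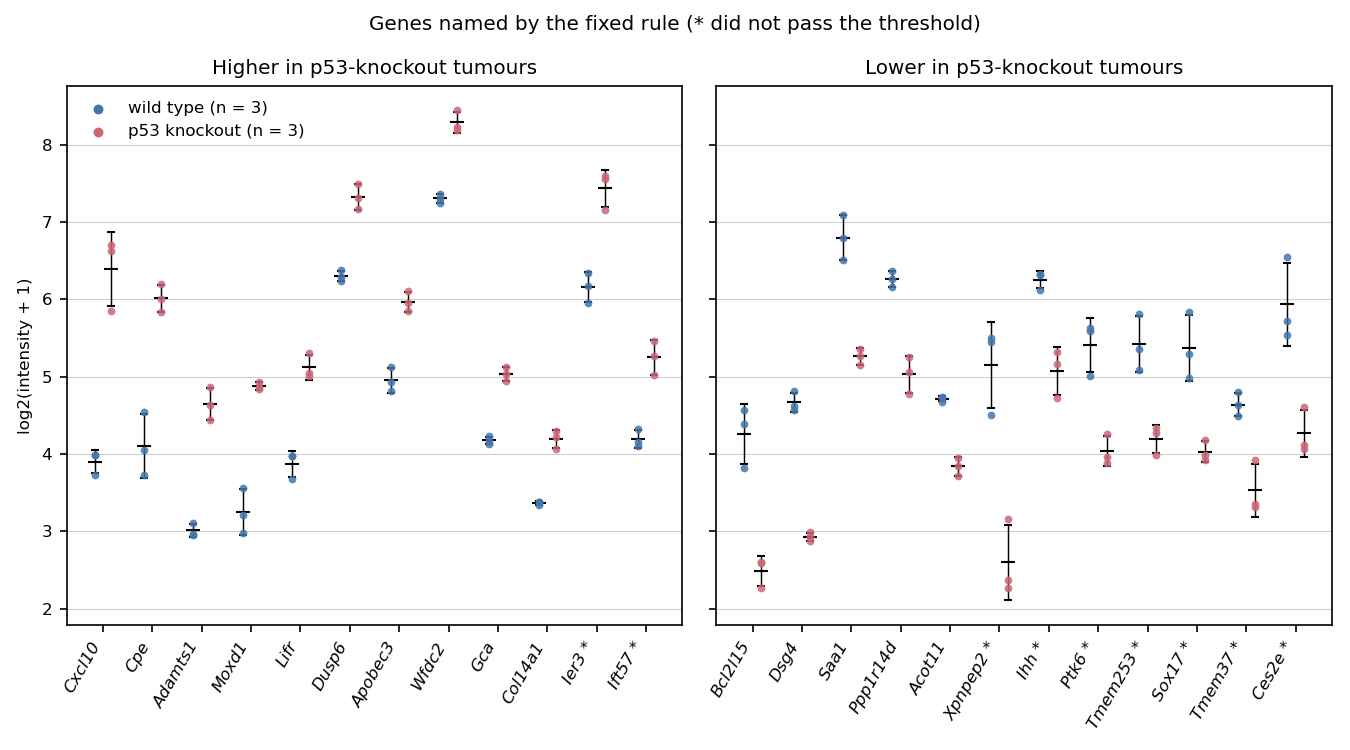
Signal as log2(intensity + 1) of the genes named by the fixed rule in each wild-type (blue) and p53-knockout (red) sample, with the mean and SD of 3 samples as black lines. Genes with an asterisk did not pass the threshold, and Cxcl10 lay at 3.90 in wild-type and 6.39 in knockout tumours.

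Genes known to be activated by p53 were lower as a list in the knockout tumours. Of 36 measured targets, 4 fell and 0 rose when adjusted over the list alone, and 0 passed over all genes tested. Ccng1, which encodes cyclin G1, fell from 7.93 ± 0.23 to 7.14 ± 0.05 (SD, n = 3 each). Eda2r, a receptor of the tumour necrosis factor family, fell by 0.60 at a dim level (from 2.47 to 1.87) and Slc19a2, a thiamine transporter, by 0.59. Ephx1, an epoxide hydrolase named after its values were seen, fell by 1.32. Mdm2 (-0.25), Bbc3 (-0.055) and Pmaip1 (-0.038), also named after their values were seen, did not pass. At an unadjusted p under 0.05 in limma 4 members were lower and 3 higher. Cdkn1a, Bax and Gdf15 were not among the measured members. The mean of the list was -0.14 (camera adjusted p = 0.0393), with adjusted p = 0.441 with an estimated correlation, and it was -0.085 with a pseudocount of 16 and -0.21 over clearly measured members. The call was lost without wild-type sample 1 (adjusted p = 0.103), wild-type sample 2 (adjusted p = 0.0771) or knockout sample 2 (adjusted p = 0.169), with samples sharing a number averaged (adjusted p = 0.0872), with a pseudocount of 16 (adjusted p = 0.058) and by ranks (adjusted p = 0.0747), and over the 21 alternatives adjusted p ran from 0.00781 to 0.504.

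Cytokines and chemokines were higher as a list in the knockout tumours, through part of their members. Of 33 measured members, 11 rose and 1 fell when adjusted over the list alone, and 0 passed over all genes. Among those that did not pass, Il6 differed by 0.28 and Tnf by 0.035, both named after their values were seen. The neutrophil-attracting chemokine Cxcl1 rose from 5.37 ± 0.26 to 6.70 ± 0.51 (SD, n = 3 each), the interleukin Il1a from 3.27 ± 0.36 to 4.43 ± 0.32 and Il23a, a subunit of interleukin 23, from 3.85 ± 0.13 to 4.42 ± 0.11. The 1 that fell was Il18, by 0.47, named after its values were seen. Of the 11 that rose, only Cxcl1, Cxcl2 and Il1b had a wild-type mean above 4. The others were dimmer there, such as Csf2 at 2.02 and Ccl2 at 3.02. Apart from Cxcl1, these were named after their values were seen. The list had a mean of 0.48 (camera adjusted p = 1.02e-07), with adjusted p = 0.322 with an estimated correlation. With a pseudocount of 16 the mean was 0.27. Neutrophil markers were higher with it, with a mean of 0.51 over 21 genes (camera adjusted p = 6.98e-06, and adjusted p = 0.441 with an estimated correlation), and with 0.29 at a pseudocount of 16. In that list 3 genes rose when adjusted over the list alone and 0 over all genes. They were the haptoglobin gene Hp (1.88), the interleukin 1 decoy receptor Il1r2 (0.54) and Ly6g (0.69), of which Hp and Il1r2 are also made by other cells and Ly6g belongs to a family of similar genes.

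Genes of NF-kappaB signalling were higher as a list. In that list 5 of 27 genes rose when adjusted over the list alone, and 0 over all genes. Ptgs2, the inducible cyclooxygenase, rose 6.06-fold from 5.18 ± 0.14 to 7.78 ± 0.76 (SD, n = 3 each), Ier3 from 6.16 ± 0.19 to 7.43 ± 0.24 and the inhibitor Nfkbie by 0.55. The list mean was 0.34 and its median 0.0973 (camera adjusted p = 3.8e-05, and adjusted p = 0.441 with an estimated correlation). Among immediate early and heat shock genes, 3 of 17 rose over the list alone and 0 over all genes, namely the nuclear receptor Nr4a1 (1.19), the phosphatase Dusp1 (0.72) and the mRNA decay factor Zfp36 (0.43). The mean of these 17 was 0.26 (camera adjusted p = 8.75e-05, and adjusted p = 0.441 with an estimated correlation).

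Interferon-stimulated genes were higher as a list, through part of their members. Of 25 genes, 4 rose when adjusted over the list alone and 1, Cxcl10, over all genes. The chemokine Cxcl9 rose by 1.32, the guanylate-binding protein Gbp3 by 0.94 and the transcription factor Irf1, named after its values were seen, by 0.36. The mean was 0.34 and the median 0.0297 (camera adjusted p = 0.00131, and adjusted p = 0.545 with an estimated correlation). Of the 25 differences, 14 were positive and 11 negative, and the list means of the groups overlapped. Without wild-type sample 3 the mean was 0.10 (adjusted p = 0.771), without wild-type sample 2 it was 0.54, and over the 21 alternatives adjusted p ran from 2.31e-07 to 0.771. The STAT3 pathway and acute phase list did not pass (camera adjusted p = 0.761), and its mean of -0.11 had the opposite sign to its median of 0.13 and to its test. Saa1 fell in it, 1 of 23 genes over the list alone and over all genes, while Lrg1 differed by -1.29 and Cebpd by 0.33 without passing.

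Matrix proteases and their inhibitors were higher as a list, through part of their members. Of 23 measured genes, 11 rose when adjusted over the list alone, and 1, Adamts1, over all genes, while Mmp7, named after its values were seen, differed by -0.29 without passing. Timp2, a metalloprotease inhibitor, rose from 4.99 ± 0.15 to 6.25 ± 0.42 (SD, n = 3 each) and the lysosomal protease Ctsl from 6.40 ± 0.17 to 7.41 ± 0.41. The list mean was 0.66 (camera adjusted p = 7.75e-10, and adjusted p = 0.426 with an estimated correlation), and relative to the wild type it was 1.04, 0.63 and 0.30 in knockout samples 1, 2 and 3. Of 23 genes of epithelial-mesenchymal transition, 8 rose over the list alone and 0 over all genes. The intermediate filament Vim rose from 7.87 ± 0.29 to 8.78 ± 0.34, fibronectin Fn1 from 7.21 ± 0.41 to 8.51 ± 0.57 and the transcription factor Twist2 by 0.32, at a dim level (2.61 to 2.94). Other members were named after their values were seen. Twist1 rose by 1.75 over the list alone, from a dim 2.86 ± 0.04 to 4.61 ± 0.98, with a wide spread in the knockout. Snai1 (0.26), Snai2 (-0.025), Zeb1 (0.20) and Zeb2 (0.11) did not pass. Their list mean was 0.62 (camera adjusted p = 6.93e-09, and adjusted p = 0.441 with an estimated correlation), and 0.40 with a pseudocount of 16. The knockout samples lay at 1.02, 0.60 and 0.24 in that list, and Vim and Fn1 are also expressed by stromal cells, whose markers follow.

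Lists of stromal cell markers were called higher with the preset correlation, with overlap between the groups. Fibroblast and matrix genes had a mean of 0.52 over 26 genes (camera adjusted p = 3.69e-08, and adjusted p = 0.441 with an estimated correlation). Thrombospondin 2, Thbs2, rose from 4.02 ± 0.38 to 5.99 ± 0.74 (SD, n = 3 each), the 1 gene past over the list alone, with 0 over all genes. Postn differed by 0.95 and Col12a1 by 1.19 without passing. The mean of the list relative to the wild type was 0.73 in knockout sample 1, 0.72 in sample 2 and 0.11 in sample 3, against an SD of 0.245 among the wild-type samples.

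Endothelial markers had a mean of 0.23 over 18 genes (camera adjusted p = 0.00153, and adjusted p = 0.487 with an estimated correlation). Smooth muscle markers had a mean of 0.36 over 19 genes (camera adjusted p = 0.025, and adjusted p = 0.545 with an estimated correlation). In both lists 0 genes passed over the list alone, with 1 endothelial and 2 smooth muscle genes at an unadjusted p under 0.05 in limma. Knockout sample 3 stood at -0.046 in the endothelial and -0.020 in the smooth muscle list, relative to the wild-type mean. The endothelial glycoprotein Eng differed by 0.77 and the filamin gene Flna by 0.65. The endothelial call was lost without wild-type sample 2 (adjusted p = 0.0589) or knockout sample 2 (adjusted p = 0.0997), and its mean was 0.38 without knockout sample 3, 0.39 over clearly measured genes and 0.11 with a pseudocount of 16. The smooth muscle call was lost without wild-type sample 2 (mean 0.22, adjusted p = 0.196), wild-type sample 3 (adjusted p = 0.0655) or knockout sample 2 (mean 0.23, adjusted p = 0.433), and its mean was 0.23 with a pseudocount of 16, 0.54 over clearly measured genes and 0.55 without knockout sample 3. Over the 21 alternatives adjusted p ran from 1.08e-07 to 0.577 for endothelial and from 0.000107 to 0.578 for smooth muscle markers.

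With the preset correlation, the lists of epithelial repair and of stem cells were called higher and that of the mature absorptive cell lower. Of 15 measured YAP and injury-repair genes, 4 rose when adjusted over the list alone and 0 over all genes. Ereg, a ligand of the epidermal growth factor receptor, rose 8.09-fold from 3.73 ± 0.67 to 6.75 ± 0.57 (SD, n = 3 each), mesothelin Msln from 3.80 ± 0.12 to 5.20 ± 0.46 and the keratin Krt17 by 1.16. The mean of the list was 0.66 (camera adjusted p = 3.74e-07, and adjusted p = 0.141 with an estimated correlation), and the knockout samples lay close together at 0.69, 0.64 and 0.64 above the wild type. Wnt target and stem cell genes had a mean of 0.33 over 24 genes (camera adjusted p = 0.000311, and adjusted p = 0.441 with an estimated correlation). The groups overlapped in that list, and 0 genes passed over the list alone (5 at an unadjusted p under 0.05 in limma), with differences of 0.92 for Smoc2, 0.41 for Sox9 and 0.37 for the stem cell receptor Lgr5.

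Of 27 measured absorptive colonocyte genes, 6 fell and 1 rose when adjusted over the list alone, and 0 passed over all genes. The adhesion molecule Ceacam20 fell from 5.68 ± 0.26 to 4.60 ± 0.32 (SD, n = 3 each) and the dehydrogenase Dhrs9 from 6.26 ± 0.15 to 5.80 ± 0.02, while the aminopeptidase Anpep rose by 0.65. The list mean was -0.40 (camera adjusted p = 1.36e-05, and adjusted p = 0.322 with an estimated correlation). Genes of all epithelial cells, a list chosen after the data were seen, had a mean of -0.23 over 23 clearly measured members, against -0.58 over the 18 clearly measured colonocyte genes. Of 25 epithelial junction genes, 3 fell and 1 rose over the list alone, and 0 over all genes. The claudin Cldn15 fell by 0.99, the tight junction scaffold Tjp3 by 0.48 and desmoplakin Dsp, named after its values were seen, by 0.34, and Cldn1 rose by 0.48 at a dim level (1.80 to 2.28). The junction list had a mean of -0.17 (camera adjusted p = 0.000997, and adjusted p = 0.486 with an estimated correlation).

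Hypoxia and glycolysis genes were slightly lower, with a mean of -0.15 over 19 genes (camera adjusted p = 0.0446, and adjusted p = 0.72 with an estimated correlation). None of them passed over the list alone, with 2 at an unadjusted p under 0.05 in limma, and Pfkl differed by -0.48, Ldha by -0.30 and Aldoa by -0.19. The call was lost without wild-type sample 2 (adjusted p = 0.0771), wild-type sample 3 (mean -0.025, adjusted p = 0.597), knockout sample 2 (adjusted p = 0.233) or knockout sample 3 (adjusted p = 0.239), with probe sets averaged (adjusted p = 0.0596) and with the shared number as a random block (adjusted p = 0.0657). Without wild-type sample 1 the mean was -0.29, and over the 21 alternatives adjusted p ran from 0.000166 to 0.72.

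**Figure D2:**
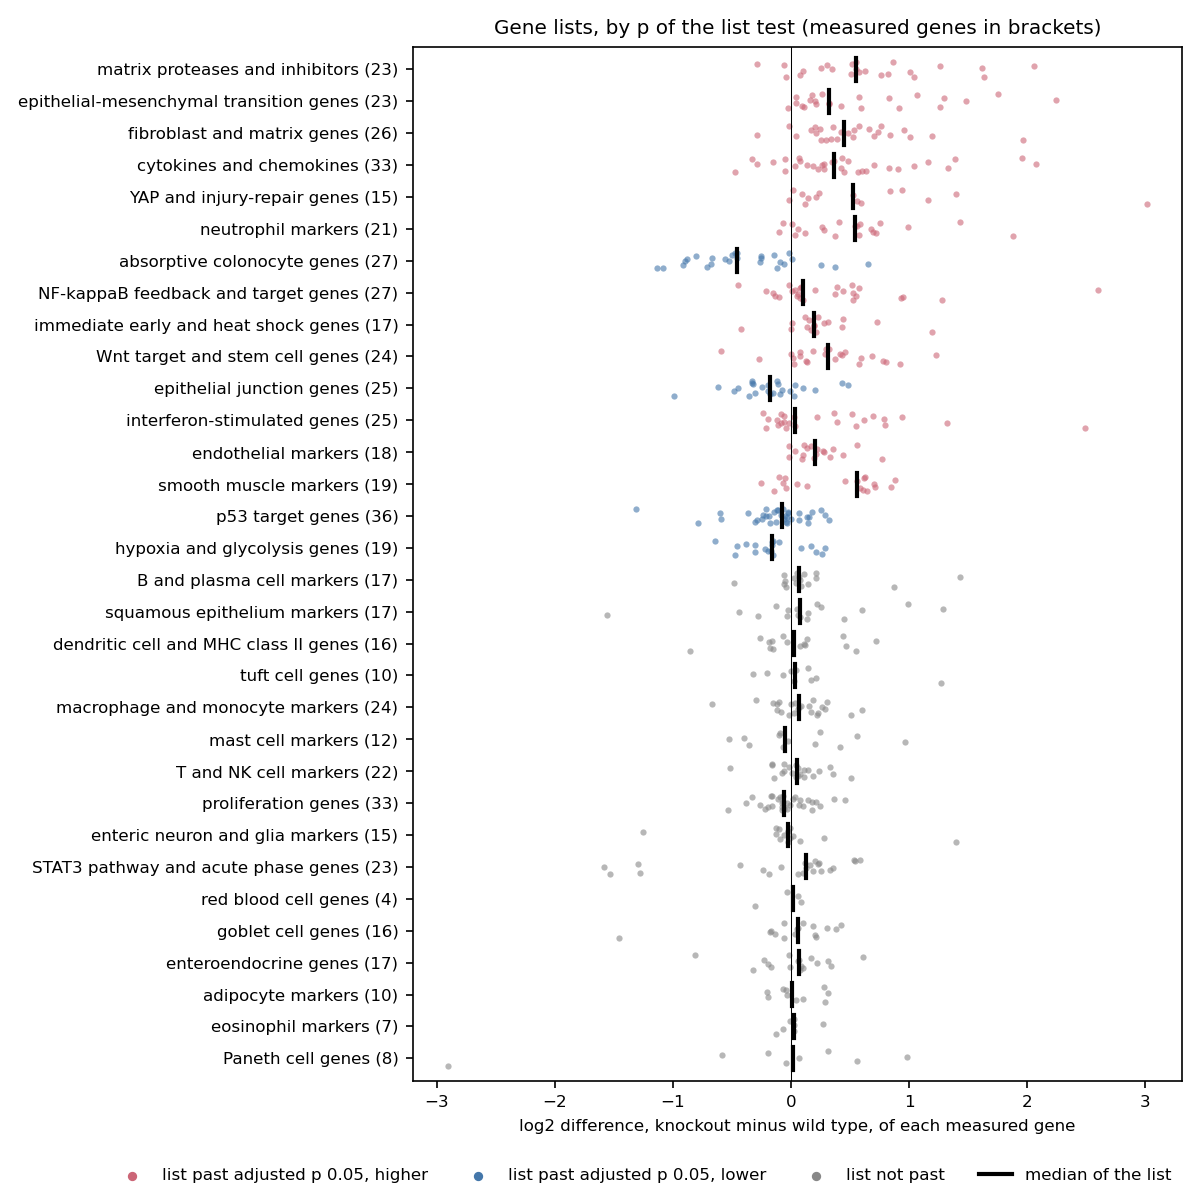
Log2 difference, knockout minus wild type, of each measured gene (points) in the 32 tested lists, ordered by p of camera with the preset correlation, with the list median as a black bar. Red and blue lists passed higher (12) and lower (4), and the 16 grey lists did not pass.

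The remaining 15 lists did not pass. Proliferation genes had a mean of -0.034 over 33 genes (camera adjusted p = 0.601), with 0 past over the list alone and 1, Ccne2 (-0.53), at an unadjusted p under 0.05 in limma. Macrophage and monocyte markers had a mean of 0.067 over 24 genes (camera adjusted p = 0.324), with values of 0.51 for Cd68, -0.67 for Nos2 and 0.60 for Mrc1, none past over the list alone. Without knockout sample 3 that list passed, with a mean of 0.15 (adjusted p = 0.00462, and 0.00462 to 0.905 over the 21 alternatives). In the list of dendritic cells and MHC class II (mean 0.045, camera adjusted p = 0.311), 3 of 16 genes rose over the list alone and 0 over all genes, and these were the class II chain H2-Aa (0.55), its invariant chain Cd74 (0.72) and H2-Ab1 (0.47). Over its 4 clearly measured members, these 3 and H2-Eb1 (-0.85, wild-type SD 1.80, named after its values were seen), the mean was 0.22 (SE over members 0.362) and passed (adjusted p = 0.000957, and 0.000957 to 0.65 over the 21 alternatives). B and plasma cell markers had a mean of 0.15 (camera adjusted p = 0.0663), with 2 of 17 up over the list alone, the antibody joining chain Jchain (1.43) and Mzb1 (0.87). That list passed in 6 of 20 alternatives, among them without wild-type sample 1 (adjusted p = 0.0125) and without knockout sample 1 (adjusted p = 0.0029), with adjusted p from 0.0029 to 0.566. T and NK cell markers had a mean of 0.048 (camera adjusted p = 0.342), with Nkg7 at 0.50 and Prf1 at -0.51, neither past over the list alone.

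Of the other immune and stromal types, mast cell markers had a mean of 0.068 (camera adjusted p = 0.342), eosinophil markers 0.020 (camera adjusted p = 0.972), adipocyte markers 0.047 (camera adjusted p = 0.861) and red blood cell genes -0.048 (camera adjusted p = 0.798). Without knockout sample 1 the mast cell list passed, with a mean of 0.36 (adjusted p = 0.00131, and 0.00131 to 0.896 over the 21 alternatives), while without knockout sample 3 its mean was -0.15. Enteric neuron and glia markers had a mean of -0.0063 (camera adjusted p = 0.657), and Uchl1, a neuronal hydrolase, rose in it by 1.40 over the list alone, while Ret differed by -1.25. Among epithelial types, the mean was -0.0065 for goblet cell genes (camera adjusted p = 0.836), 0.016 for enteroendocrine genes (camera adjusted p = 0.861), 0.13 for tuft cell genes (camera adjusted p = 0.324), -0.23 for Paneth cell genes (camera adjusted p = 0.972) and 0.10 for squamous markers (camera adjusted p = 0.296). The goblet mean rested on wild-type sample 1, which stood at 0.667 against -0.393 and -0.274 in the other wild-type samples, and without it the list passed higher with a mean of 0.33 (adjusted p = 0.000223, and 0.000223 to 0.981 over the 21 alternatives). The Paneth mean was 0.042 without wild-type sample 1 and -0.54 without wild-type sample 3, and the list did not pass in any alternative. Hpgds, a prostaglandin D synthase of the tuft list, rose by 1.27 over the list alone. The goblet gene Clca1 differed by -1.45 and the Paneth list member Mptx1 by -2.91, neither past over its list alone. In the squamous list the keratin Krt5 differed by 1.29 and Dsg3 by -1.56, neither past over the list alone. Mean and median differed in sign for mast cell, red blood cell, goblet and Paneth lists, and the goblet test had the sign of its median.

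With an estimated correlation 0 of the 32 lists passed in camera (3 at an unadjusted p under 0.05), and 0 passed in fry (4 unadjusted), which asks only whether a list's genes moved one way on balance. By ranks 15 passed. Sex-linked genes did not separate the groups, with Xist at 1.96 ± 0.24 and 1.98 ± 0.21, Eif2s3y at 5.94 ± 0.03 and 5.99 ± 0.19, and Uty at 4.36 ± 0.11 and 4.38 ± 0.18 in wild-type and knockout tumours (SD, n = 3 each).

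**Figure D3:**
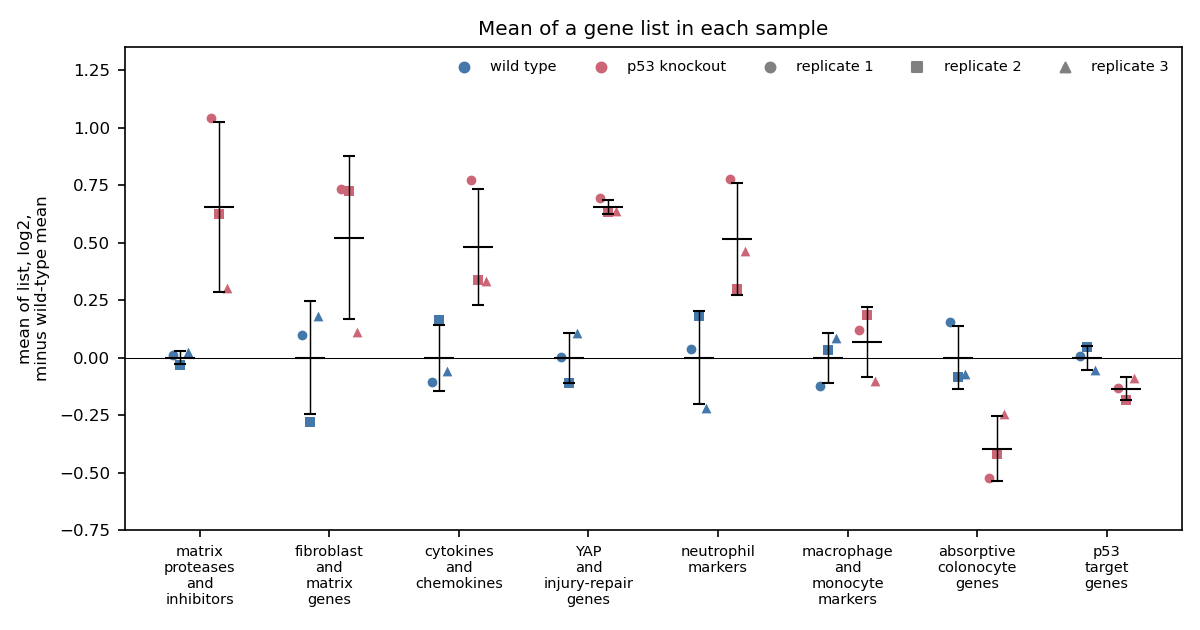
Mean log2 signal of 8 gene lists in each sample, relative to the mean of the 3 wild-type samples, with group mean and SD as black lines. In the fibroblast list knockout sample 3 lies at 0.11, below samples 1 and 2 at 0.73 and 0.72, and in the YAP list the knockout samples lie between 0.64 and 0.69.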

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

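The tests of cell composition, of knockout sample 1 alone, of the genes beside called genes and of signal near the floor were chosen after the values they bear on had been seen.

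Among probe sets outside the comparison of named genes, 3 passed adjusted p 0.05 when all probe sets were tested together, which is a signal in data the gene comparison did not use. One is listed for several genes and differed by 1.91. The other two are not listed and are unnamed here, one with a difference of 1.43 and one with -2.62.

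With the preset correlation the matrix and fibroblast lists were called higher and the colonocyte list lower in the knockout tumours, but with an estimated correlation 0 of the 32 lists passed (3 at an unadjusted p under 0.05 in camera), and the groups overlapped in the fibroblast list. Loss of epithelium as the whole cause of the lower colonocyte list would lower all epithelial genes as much. Over clearly measured genes only, the mean was -0.234 for 23 pan-epithelial genes but -0.583 for 18 colonocyte genes. The former thus lay 0.349 above the latter (SE over genes 0.0849, 95% interval from the spread between samples 0.049 to 0.65). That interval takes the 6 samples as separate animals and was not computed with shared numbers averaged. Knockout sample 1 was the farthest from the wild type. With the preset correlation all 16 lists stayed past the threshold in the same direction without it, so it did not carry those calls alone. That is weak evidence, as other splits of the samples gave up to 15 lists. Without it the mean was 0.464 in place of 0.655 for matrix proteases and 0.417 in place of 0.522 for fibroblasts, but 0.637 in place of 0.655 for the YAP list. The gene count was 2, with 1 of the 17 among them. Fewer epithelial cells as the cause of the higher matrix lists stay open: clearly measured genes shifted by 0.719 for neutrophils, 0.624 for fibroblasts, 0.54 for smooth muscle, 0.394 for endothelium and 0.107 for macrophages, and fibroblasts minus macrophages gave 0.517 (SE over genes 0.133), but with an interval of -0.197 to 1.23 from the spread between samples. Pan-epithelial genes shifted by -0.234, and more fibroblasts, the part of the tumour that was sampled and the genotype itself were not tested apart.

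Dsg4 differed as a step with little spread within groups. In the other called genes the groups did not overlap either, but some spread more widely, such as Cxcl10 in the knockout (SD 0.47) and Cpe in the wild type (SD 0.41). Of the 50 measured genes on either side of the floxed gene, 7% were at an unadjusted p under 0.05 in limma. Random places gave a median of 11% and a central range of 4% to 18%. That argues only against a strain segment carried along with the floxed gene that moved many genes there. A segment altering few genes would not raise such a share, so it stays open. For local variants beside called genes, 7.94% of their 10 neighbours on either side moved the same way at an unadjusted p under 0.05, against a median of 5.59% and a central range of 2.99% to 8.55% for random genes, and around Dsg4 alone 4 of 20 did (20%, percentile 95.9 of random genes), namely Dsg3, Mep1b, Dsc2 and Dsg2, while Kctd1 (0.59) and Rnf138 (0.29) moved the other way at such a p. A value within that range had been set as evidence against such variants, but as 7.94% lay at percentile 93 the reading was changed after it was seen, and they cannot be told apart from an effect of the genotype. Signal near the floor is argued against as the whole cause, since 8 of the 17 genes were clearly measured in both groups, among them Wfdc2 at 7.30 and 8.29 and Dusp6 at 6.30 and 7.32. For the other 9, not clearly measured in 1 of the groups, it stays open. In their lower group 13 of the 17 lay above the median of all genes (3.31) and 4 under it, but that median is not a detection limit.

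With 10 splits of the 6 samples, no share under 0.05 can be reached. The real split, 1 of the 10, gave 17 genes and the highest other split 0. For lists the real split gave 16, more than the highest other split with 15, so that 1 of the 10 splits gave as many.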

How the results depend on the processing

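The tests on clearly measured members and on lists with an estimated correlation without knockout sample 1 were chosen after seeing the data. The planned value of the targeted gene was not run. The count of 17 genes became 11 with quantile normalization, 46 without dim probe sets and 52 with a trend and robust eBayes (fewer genes or another variance model), 36 at an adjusted p under 0.1, 5 over all probe sets, 34 with the shared number as a random block (consensus correlation -0.251), and 0 with shared numbers averaged or with a pseudocount of 16 (2015 and 1952 genes at an unadjusted p under 0.05 in limma). The cause was not tested. Leaving out 1 sample gave 1 to 16 genes, with 1 to 7 of the 17 among them. Centring gave 14, averaged probe sets 13 and array weights 17. In the 16 refits by gene the 17 genes kept their sign and an unadjusted p under 0.05. That is no separate evidence, as the genes were chosen on these samples. Leaving out a sample also cannot change the sign where groups do not overlap.

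The replicate numbers did not pair the samples: deviations of same-numbered samples correlated at 0.0039, -0.058 and 0.053, and not every sample correlated best with its own number. The replicate block gave 0 genes (2184 at an unadjusted p under 0.05) and 16 lists. Samples sharing a number had the highest r within their group. It was 0.9879 for wild-type samples 1 and 2, against 0.9865 and 0.9867 for the other wild-type pairs. For knockout samples 2 and 3 it was 0.9914, against 0.9885 and 0.9901. Such small differences do not settle whether the number is an animal.

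The 16 lists fell to 0 with an estimated correlation, to 0 by fry, and to 0 with an estimated correlation without knockout sample 1 (3, 4 and 4 at an unadjusted p under 0.05). In the other settings 12 to 18 lists passed, and the 16 kept their direction in all. Beyond the 16, B and plasma cell markers passed in 6 of 20 alternatives, and macrophage, mast cell, dendritic cell and goblet lists in 1 of 21 each. With a pseudocount of 16 the 17 genes kept 41.5% to 93.6% of their log2 difference (median 61.8%), as with -0.838 in place of -1.74 for Dsg4, 0.799 in place of 1.64 for Adamts1, 0.901 in place of 1.02 for Dusp6 and 0.92 in place of 0.983 for Wfdc2, and their adjusted p lay between 0.0818 and 0.217; whether dim signal ended the calls was not tested.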

Other observations

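All 4 lists tested here were chosen after the main result was seen, and the value of Egr1 in the MAP kinase list was known beforehand. Values of its members Ccnd1 and Fosl1 had also been computed before, in the fixed lists.

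Beside Ighm, other immunoglobulin genes were tested as a list, without Igkv10-96, whose value had been seen. All 9 that were measured had a positive difference between knockout and wild-type tumours, with values of up to 1.65 and the IgA heavy chain Igha at 0.896, and 2 of the 9 were at an unadjusted p under 0.05 in limma. Their mean was 0.805, with p = 0.137 with an estimated correlation, so more antibody-producing cells may be present, but these genes vary together (estimated correlation 0.56) and the test leaves it open.

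Interferon-inducible GTPases, which act in cell-autonomous defence, were tested as a hypothesis drawn from Cxcl10 and from Iigp1, which differed by 1.98 without passing (adjusted p = 0.0686). Gbp3 and Gbp7, whose values had been seen, were left out too. All 5 other measured members had a positive difference, with a mean of 0.661, Gbp4 at 1.12 and Irgm1 at 0.713. The list had p = 0.02 with an estimated correlation, and adjusted p = 0.0801 over the 4 lists, so it fails the correction. A stronger response to interferon may underlie these values, which stays a hypothesis. In the fixed list of interferon-stimulated genes the median was 0.0297, with 14 of 25 differences positive and 11 negative. Ifit1 (-0.19), Rsad2 (-0.063) and Oas1a (-0.11), named after their values were seen, did not rise. That list did not pass without wild-type sample 3 (camera adjusted p = 0.771), and the GTPase list was not refitted without that sample.

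Dusp6 is induced by ERK signalling as part of its feedback, which suggests testing the other feedback genes. Of 15 such genes 13 had a positive difference and 6 were at an unadjusted p under 0.05, among them Phlda1 at 0.817, Spry4 at 0.882 and Spry2 at 0.541, while the target Ccnd1 was at -0.274. The mean was 0.347, with p = 0.0519 with an estimated correlation and adjusted p = 0.104, which leaves the hypothesis open.

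Tumours from other positions along the colon could also differ, since Slc10a2, the ileal bile acid transporter, differed by -1.69 (SE 0.584) without passing (adjusted p = 0.359). Posterior Hox genes, which follow that position, had a mean of 0.204 over 11 genes (95% interval over genes -0.0457 to 0.454), with 0 at an unadjusted p under 0.05 in limma and p = 0.577 for the list with an estimated correlation. Hoxd13 differed by 0.96 (SE 1.05), so the position stays open.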
